A study of Mus musculus with 8 samples.

How the data were processed

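Plasma RNA of female mice aged 3 months was measured on 8 one-colour miRNA arrays, each with RNA from 300 µl of plasma pooled from 3 mice and 3.1 µl of RNA labelled with Cy3. The labels call the pools biological replicates. All arrays lie on 1 slide, so slides could not differ. DOX pools 1 and 2, IMB pool 1 and CTRL pool 1 lie in row 1 of the slide and the other pools in row 2. The number of arrays limits the precision of every value.

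The deposited scanner files hold spot intensity on the linear scale, extracted with Agilent Feature Extraction 11.5.1.1 per the labels. Per the file headers the processed intensity is background-subtracted, with no scaling between arrays, and it differed from the background-subtracted column by at most 0.05. Each file holds 58594 spots, 56430 of them non-control, for 4415 probes with 7 to 30 spots each. A deposited table by the authors holds log2 values in 1902 rows. Its processing is not given in the sources used here. From its values it appears to be the log2 of Agilent's total signal per miRNA after quantile normalization, since it ranks detected miRNAs as that signal does (Spearman rho 1) and its highest 300 values are equal on all arrays. Its medians were -3.20, -3.25 and -3.23 for DOX, -3.23, -3.32 and -3.29 for IMB, and -3.28 and -3.32 for CTRL. These medians differ between arrays, so how low values were normalized is not established. The authors' values served as an alternative.

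Processed signals were averaged over the non-outlier spots of a probe. A probe was called detected where over 50% of its kept spots were well above background, and a miRNA where at least 1 of its probes was. Each array was scaled to its 75th percentile over the 454 probes detected on all 8 arrays. Probes of a miRNA were averaged on the linear scale, floored at 21.1 (log2 4.40, the median over arrays of the 1st percentile of detected probes) and put on the log2 scale. Values at the floor have no order. No spot was saturated. Tested were the 294 mouse miRNAs detected on every array of at least 1 group. Of these, 262 had a gene of that name in a RefSeq table; no coordinates were used.

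Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 2-sided) on all 8 arrays, which share an estimate of the spread because there are 2 controls, with Benjamini-Hochberg adjustment within each comparison and a threshold of 0.05. Residual degrees of freedom were 5 and prior degrees of freedom 0.605. Lists were tested with limma's camera at its preset correlation, adjusted over 16 lists and 3 comparisons, 48 tests. Of 18 lists, those of brain and of the Dlk1-Dio3 imprinted cluster had 1 tested member each, under the minimum of 3. Values per array were compared by exact permutation. Simulations with unchanged groups numbered 1000 for the correlation of the drugs' differences. Figures were drawn with matplotlib 3.10.9.

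Groups, tests, lists, named miRNAs and alternatives were fixed before the data were examined. The rule named, per comparison, miRNAs past the threshold whose groups did not overlap, up to 10 per direction by size of change. Where under 10 passed, those with the smallest unadjusted p and groups that did not overlap filled up to 10 per direction. Up to 4 members per list and a fixed set of markers of muscle, liver, red cells, myeloid cells, lymphocytes and p53 response were added. Leaving out miRNAs with a value at the floor was chosen after seeing the data. Other alternatives covered the signal used, background, scaling, filter, floor, probe summary, variance model, blocks, the red cell index as a covariate, the authors' table and leaving out each array. The normexp alternative used the median spot signal, and the mean spot signal was not used here. Scaling to reference miRNAs used miR-23a-3p and miR-24-3p, since the third one planned was not detected on all arrays.

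The steps were tested on simulated data. With 20 miRNAs changed per drug, imatinib against control recovered 70.0% of those changed by 2 log2 units and 77.8% of those changed by 1, doxorubicin against control 90.0% and 30.0%, and imatinib against doxorubicin 85.0% and 52.6%. The share of calls that fell on unchanged miRNAs exceeded the nominal 5%: it was 46.2% (12 of 26 calls), 47.8% (11 of 23) and 10.0% (3 of 30). With 60 changed per drug it was 7.84%, 15.1% and 9.09%. An earlier simulation with 60 changed per drug also exceeded 5%, and the smaller setting and the simulations with no change were added after it. Of 50 simulations with no change, 44, 43 and 48 gave no call, and 0, 7 and 0 gave as many calls as measured. Their noise was independent between miRNAs, so 0 of 50 does not show that the measured calls exceed chance. In a simulation that moved 1 list by 1 log2 unit, that list was called and 0 of the others were. Its noise was independent between miRNAs, so it does not test lists whose members vary together. In the data the estimated correlation within a list ran from -0.02 (endothelial) to 0.98 (muscle). The endothelial list also lost its calls with an estimated correlation, so such a loss need not come from members that vary together.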

Results

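Circulating miRNAs were measured in plasma of female NMRI mice, an outbred laboratory stock, after treatment with imatinib, a tyrosine kinase inhibitor, or doxorubicin, an anthracycline that damages DNA. Imatinib (IMB) was given by mouth at 100 mg/kg daily for 9 days, and doxorubicin (DOX) into the tail vein at 3 mg/kg in 4 doses on alternate days. Control mice (CTRL) received solvents only. Each array held plasma RNA from a pool of 3 mice, with 3 pools for DOX, 3 for IMB and 2 for CTRL. Of 1881 mouse miRNAs on the array, 357 were detected on at least 1 array, 245 on all 8, and 294 entered the tests. The question was which plasma miRNAs differ after each drug, and where imatinib differs from doxorubicin. Values are log2 scaled signals unless stated otherwise, and errors of differences are standard errors (SE).

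The number of miRNAs detected was 269.3 ± 10.6 (SD, n = 3 pools) for DOX, 303.0 ± 36.5 (SD, n = 3 pools) for IMB and 312.0 ± 21.2 (SD, n = 2 pools) for CTRL. DOX and CTRL differed by -42.7 miRNAs (exact 2-sided permutation p = 0.1, the smallest that 3 against 2 pools can give). IMB and CTRL differed by -9.00 (exact permutation p = 0.9), and IMB and DOX by 33.7 (exact permutation p = 0.3). Leaving out 1 pool gave -57.7 to -27.7 for DOX minus CTRL, -27.0 to 9.50 for IMB minus CTRL and 15.7 to 52.2 for IMB minus DOX. The 75th percentile of the signal before scaling was 213, 249 and 267 in the DOX pools, 196, 425 and 320 in the IMB pools, and 300 and 349 in the CTRL pools.

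The red cell index is the log2 signal of miR-451a, an abundant red cell miRNA, minus that of miR-23a-3p. A difference in the index can come from either miRNA. It was 4.09 ± 0.32 (SD, n = 3 pools) with imatinib, 3.51 ± 0.47 (SD, n = 2 pools) in controls and 2.85 ± 0.26 (SD, n = 3 pools) with doxorubicin. Each IMB pool lay above each DOX pool, by 1.23 on average (exact 2-sided permutation p = 0.1, the smallest possible). A model with the index as a covariate can therefore hardly separate it from the drug, and a call lost there does not show its cause. For the index, IMB minus CTRL was 0.57 (exact permutation p = 0.1) and DOX minus CTRL was -0.66 (exact permutation p = 0.2). Leaving out 1 pool gave 0.24 to 0.90 and -0.99 to -0.33.

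After imatinib, miR-144-3p, an erythroid miRNA, rose 1.76-fold against the controls (log2 0.82, SE 0.07, limma adjusted p = 0.0077). miR-7058-5p rose 5.26-fold (log2 2.39, SE 0.23, limma adjusted p = 0.0077), from 4.68 ± 0.21 (SD, n = 2) to 7.08 ± 0.23 (SD, n = 3). miR-202-3p rose 1.45-fold (log2 0.54, SE 0.05, limma adjusted p = 0.0077), from 4.51 ± 0.01 (SD, n = 2) to 5.04 ± 0.03 (SD, n = 3), near the floor of 4.40. With normexp background correction the difference was 0.19 for miR-202-3p (adjusted p = 0.88, not past the threshold; range over its alternatives 0.0041 to 1) and 1.19 for miR-7058-5p, whose call was lost with the replicate block (adjusted p = 0.093; range over its alternatives 0.00013 to 0.51). For each of these 3 miRNAs, all 3 IMB pools lay above both control pools. No miRNA fell past the threshold in limma.

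The muscle miRNAs miR-1a-3p and miR-133b-3p, enriched in heart and skeletal muscle, differed from the controls by 2.62 (SE 1.22) and 2.16 (SE 0.95), neither past the threshold (limma adjusted p = 0.74 and 0.68). miR-133a-3p, also of muscle, was detected on 1 of the 2 control arrays, so the size of its difference is not given, and it did not pass (limma adjusted p = 0.76). miR-1a-3p was 6.86, 9.02 and 5.16 in the IMB pools, and both miR-1a-3p and miR-133a-3p were at the floor in both control pools, so the difference of miR-1a-3p depends on the floor. The other 7 members of the list were not tested, among them miR-208a-3p and miR-499-5p, which lie in myosin genes and were not well above background on any array. As a set the muscle list did not pass (median 2.16, camera adjusted p = 0.051; adjusted p = 0.60 with an estimated correlation). It passed with no scaling, quantile normalization, median scaling, the percentile over all probes or Agilent's signal per miRNA, and without IMB pool 3 (median 2.98, adjusted p = 0.0055). miR-122-5p, the main liver miRNA, differed by 0.65 (SE 0.61), and 0 of 6 tested members of the liver list passed in limma.

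The myeloid list, with miR-223-3p at -0.27 (SE 0.18) and miR-21a-5p at -0.44 (SE 0.27), fell as a set by camera (median -0.27, adjusted p = 0.043; adjusted p = 0.60 with an estimated correlation). The endothelial list, with miR-126a-5p at -0.34 (SE 0.14), fell as a set (median -0.21, adjusted p = 0.043; adjusted p = 0.50 with an estimated correlation). The miR-29 family, with miR-29a-3p at -0.36 (SE 0.18), fell as a set (median -0.36, adjusted p = 0.047; adjusted p = 0.58 with an estimated correlation). No member of these lists passed over all miRNAs or adjusted over the list alone. The myeloid call was lost with quantile normalization or Agilent's signal and without CTRL pool 1, DOX pools 2 or 3, IMB pool 2 (median -0.15, adjusted p = 0.18) or IMB pool 3; the miR-29 call with each of 4 other scalings or Agilent's signal and without IMB pools 1 or 2, DOX pool 2 or CTRL pool 2; and the endothelial call with no scaling, the percentile over all probes, Agilent's signal or the replicate block (adjusted p = 0.057) and without any single pool other than IMB pool 3. With the red cell index as a covariate all 3 calls were lost, with medians of -0.02 for the myeloid list, -0.12 for the endothelial list and -0.06 for the miR-29 family.

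In the red cell list 1 of 8 members, miR-144-3p, passed, and the list did not pass as a set (median 0.06, adjusted p = 0.24), while it did with the replicate block (adjusted p = 0.023) and without CTRL pool 1 (median 0.31, adjusted p = 0.00088). In the miR-30 family miR-30c-5p (0.27, SE 0.06) passed adjusted over the list alone, and 0 members passed over all miRNAs. The lymphocyte, platelet, miR-17 cluster, mesenchymal, p53-responsive, liver, miR-30, let-7, epithelial and miR-15 and miR-16 lists, and the list of array-bright or doubtful entries, did not pass, with camera adjusted p from 0.18 to 0.69. The lymphocyte list (median -0.36) passed with no scaling, with the percentile over all probes and without IMB pool 1 (median -0.70, adjusted p = 0.0056). The miR-17 clusters (median -0.10) passed without IMB pool 1 (median -0.31, adjusted p = 0.028) or CTRL pool 2 (median -0.27, adjusted p = 0.037), and the mesenchymal list without IMB pool 3 (adjusted p = 0.035). The lymphocyte and myeloid lists share miR-146a-5p and miR-155-5p. The red cell index was 0.57 higher in the IMB pools than in the controls.

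At an unadjusted p under 0.05, limma gave 16 higher and 7 lower miRNAs. Chance gives at most 20% of miRNAs with groups that do not overlap, and less where values tie at the floor. The measured share was 17.7% of the 294 miRNAs. Among these, miR-5100 differed by 1.43 (SE 0.37, adjusted p = 0.26), miR-6354 by 1.51 (SE 0.37, adjusted p = 0.25), miR-1224-5p by -0.67 (SE 0.15, adjusted p = 0.21) and miR-128-3p, the only tested member of the brain list, by -0.77 (SE 0.20, adjusted p = 0.26). Doxorubicin against the same controls gave 1.04 (SE 0.37) for miR-5100, -0.54 (SE 0.15) for miR-1224-5p and -0.35 (SE 0.20) for miR-128-3p, none past the threshold. miR-494-3p, the only tested member of the Dlk1-Dio3 imprinted cluster, differed by -0.06 (SE 0.45). The count of 3 became 0 with the percentile over all probes, no scaling, scaling to miR-23a-3p and miR-24-3p, no filter or the red cell index as a covariate, which lowered miR-144-3p from 0.82 to 0.74 (adjusted p = 0.077; range over its alternatives 0.0050 to 1), and it was 1 to 5 under each of the other alternatives. It was 12 without IMB pool 1, 0 without IMB pool 2 or IMB pool 3, and 1 without CTRL pool 1 or CTRL pool 2.

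**Figure D1:**
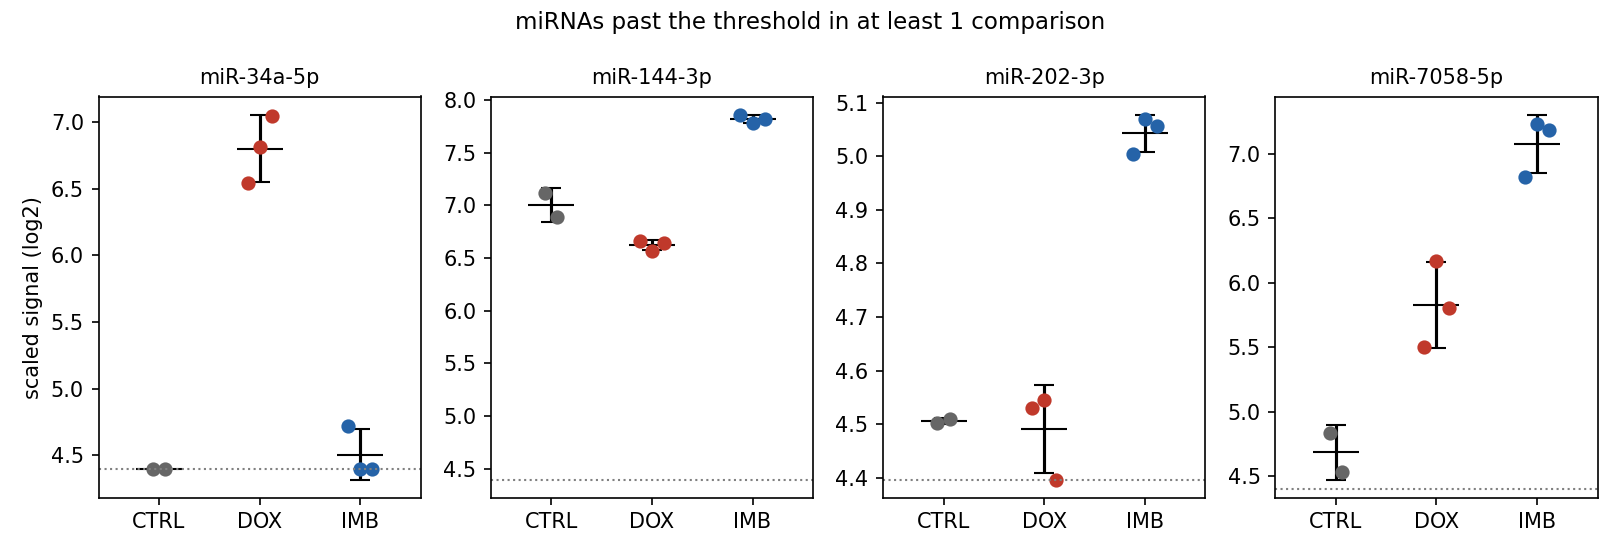
Scaled signal (log2, vertical axis) of miR-34a-5p, miR-144-3p, miR-202-3p and miR-7058-5p by group; points are pools, horizontal bars means, whiskers SD and the dotted line the floor. miR-34a-5p lies at 6.54 to 7.05 in the DOX pools and at the floor of 4.40 in both control pools, and miR-144-3p is highest in the IMB pools.

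After doxorubicin, miR-34a-5p, a transcriptional target of p53, rose 5.30-fold against the controls (log2 2.41, SE 0.17, limma adjusted p = 0.0043). It was 6.54, 6.82 and 7.05 in the 3 DOX pools, all above both control pools. Both control values were at the floor of 4.40, so the fold depends on the floor and the control SD of 0 understates the error. With a floor 4 times lower the log2 difference was 2.64, and with normexp background correction it was 1.09. No miRNA fell past the threshold in limma.

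The epithelial list rose as a set after doxorubicin by camera (median 0.46, 7 of 7 members higher, adjusted p = 0.00010; adjusted p = 0.52 with an estimated correlation). miR-429-3p (0.60, SE 0.13), miR-200b-3p (0.57, SE 0.13), miR-200a-3p (0.45, SE 0.14) and miR-205-5p (1.03, SE 0.28), miRNAs of epithelial cells, passed adjusted over the list alone, and 0 members passed over all miRNAs. The red cell list fell as a set (median -0.45, 0 of 8 members higher, adjusted p = 2.1e-05; adjusted p = 0.52 with an estimated correlation). miR-144-3p (-0.38, SE 0.07) and miR-15b-5p (-0.48, SE 0.11) passed adjusted over the list alone, and 0 members passed over all miRNAs. miR-451a was at -0.47 (SE 0.29) and miR-16-5p, also abundant in red cells, at -0.44 (SE 0.24), neither past the threshold. The red cell median was -0.22 without CTRL pool 1 and -0.69 without CTRL pool 2, both past the threshold. The red cell index differed by -0.66 between the DOX and control pools, where its reference miR-23a-3p differed by 0.19 (SE 0.15).

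The miR-17 cluster and its paralogs fell as a set (median -0.42, adjusted p = 7.7e-05; adjusted p = 0.52 with an estimated correlation), as did the miR-15 and miR-16 family (median -0.38, adjusted p = 0.0094; adjusted p = 0.50 with an estimated correlation) and the let-7 family (median -0.26, adjusted p = 0.025; adjusted p = 0.52 with an estimated correlation). No member passed over all miRNAs. Adjusted over the list alone, miR-15b-5p and let-7i-5p (-0.37, SE 0.06) passed. The red cell list shares miR-25-3p, miR-92a-3p and miR-106b-5p with the miR-17 clusters, and miR-15b-5p and miR-16-5p with the miR-15 and miR-16 family. The let-7 call was lost with no scaling (adjusted p = 0.47), quantile normalization (0.15), the percentile over all probes (0.18) or Agilent's signal (0.14), and without IMB pool 1 (0.077), and its median was -0.10 without DOX pool 1 and -0.13 without CTRL pool 1 or CTRL pool 2. Without CTRL pool 1 the median was -0.24 for the miR-17 clusters and -0.14 for the miR-15 and miR-16 family, both past the threshold. The miR-15 and miR-16 call was lost with no scaling (adjusted p = 0.072) or Agilent's signal (0.073) and without DOX pool 2 (0.078). With the red cell index as a covariate all 5 list calls were lost. The red cell list holds miR-451a of the index, so its loss there is no independent test. With the covariate the medians were -0.13 for the red cell list, 0.32 for the epithelial list and -0.23 for the miR-17 clusters. They were -0.21 for the miR-15 and miR-16 family and -0.11 for let-7.

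Of 7 tested members of the p53-responsive list, miR-34a-5p passed; miR-194-5p differed by 0.59 (SE 0.30) and miR-192-5p by 0.41 (SE 0.22), both shared with the liver list. As a set it did not pass (median 0.23, camera adjusted p = 0.0503; adjusted p = 0.52 with an estimated correlation), and fry's test of change in either direction gave an adjusted p of 0.00050. It passed without DOX pool 1 (median 0.42, adjusted p = 0.018), DOX pool 2 (adjusted p = 0.045) or CTRL pool 2 (median 0.40, adjusted p = 0.034), with quantile normalization or Agilent's signal, and with no scaling, where its median was -0.20. miR-1a-3p was 7.02, 5.04 and 5.04 in the DOX pools (1.30, SE 1.22, not past the threshold), and the muscle list did not pass (median 1.30, adjusted p = 0.29) except with no scaling (median 1.05, adjusted p = 0.0057).

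miR-122-5p differed by 0.70 (SE 0.61), miR-150-5p, a lymphocyte miRNA, by -0.29 (SE 0.42), miR-223-3p by 0.21 (SE 0.18), miR-128-3p of the brain list by -0.35 (SE 0.20) and miR-494-3p of the Dlk1-Dio3 cluster by -0.25 (SE 0.45), none past the threshold. The liver, endothelial, lymphocyte, platelet, miR-30, myeloid, miR-29 and mesenchymal lists, and the list of array-bright or doubtful entries, did not pass, with camera adjusted p from 0.17 to 0.94. The liver list passed without DOX pool 1 (adjusted p = 0.026), and the lymphocyte list without IMB pool 1 (adjusted p = 0.028) and with no scaling.

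At an unadjusted p under 0.05, limma gave 15 higher and 10 lower miRNAs, and the groups did not overlap for 28.6% of miRNAs. Chance gives at most 20%, and less where values tie at the floor. The miRNAs are not independent, and the excess was not tested. In 7 of 50 simulations with no change, at least as many miRNAs as the 1 measured passed. The call of miR-34a-5p was lost with no filter, only the compared groups in the fit, the replicate block, the red cell index as a covariate (2.20, adjusted p = 0.094; range over its alternatives 0.00033 to 0.14) and without CTRL pool 1 (adjusted p = 0.080). The count was 2 without IMB pool 1 or CTRL pool 2, and 2 with Agilent's signal, the percentile over all probes, a lower floor or the authors' table.

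**Figure D2:**
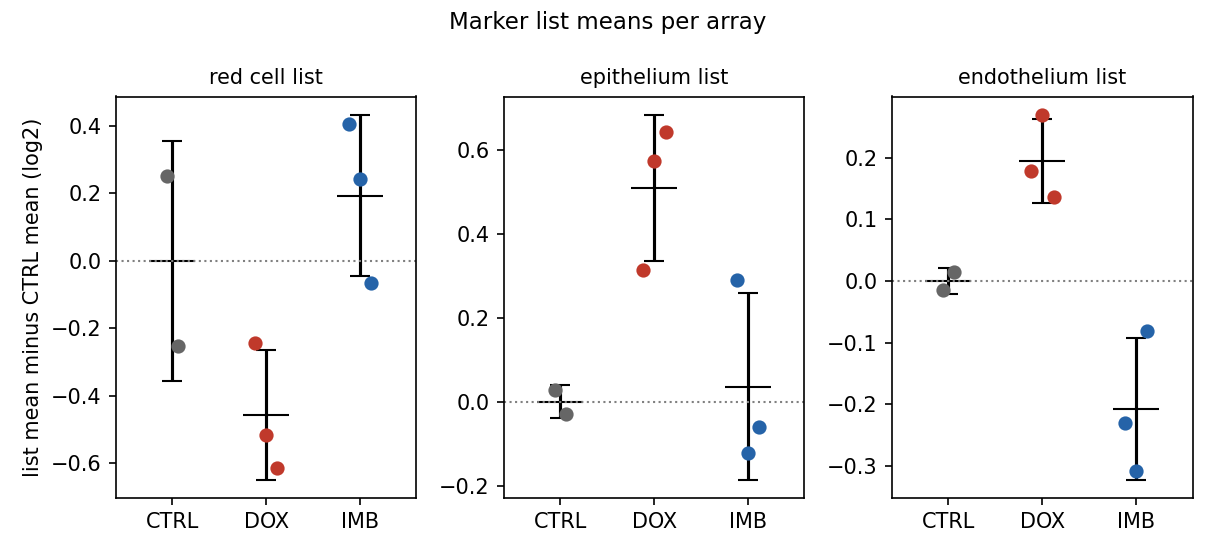
Mean log2 signal of the red cell, epithelial and endothelial lists minus the mean over the control pools (vertical axis) by group; points are pools, horizontal bars means, whiskers SD and the dotted line 0. The DOX pools lie at -0.24 to -0.61 for the red cell list and at 0.31 to 0.64 for the epithelial list.

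Between the drugs, miR-144-3p was 2.30-fold higher with imatinib than with doxorubicin (log2 1.20, SE 0.06, limma adjusted p = 0.00090), at 7.82 ± 0.04 (SD, n = 3) against 6.62 ± 0.05 (SD, n = 3). miR-202-3p was higher past the threshold (limma adjusted p = 0.0029), but it was detected on 1 of the 3 DOX arrays, so the size of the difference is not given, and with normexp background correction it did not pass (adjusted p = 0.93; range over its alternatives 0.0012 to 0.93). miR-34a-5p was lower with imatinib at -2.30 (SE 0.15, limma adjusted p = 0.0015), at the floor in 2 of the 3 IMB pools. With normexp the difference was 0.78 for miR-144-3p and -0.98 for miR-34a-5p, both past the threshold. For each of these 3 miRNAs the groups did not overlap. This comparison is also the test of whether the drugs' differences from the controls differ.

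The red cell list was higher with imatinib as a set (median 0.54, 8 of 8 members higher, adjusted p = 6.1e-06; adjusted p = 0.52 with an estimated correlation). miR-144-3p passed over all miRNAs, and 5 members passed adjusted over the list alone, among them miR-451a (0.84, SE 0.26) and miR-25-3p (0.58, SE 0.20). The epithelial list was lower (median -0.33, adjusted p = 0.00092; adjusted p = 0.52 with an estimated correlation; median -0.22, adjusted p = 0.014, without DOX pool 3), with miR-205-5p at -1.44 (SE 0.25, limma adjusted p = 0.072). The endothelial list was lower (median -0.35, adjusted p = 0.0022; adjusted p = 0.50 with an estimated correlation), with miR-126a-5p at -0.69 (SE 0.13, limma adjusted p = 0.086). Adjusted over the list alone, those members passed, 1 in each list. The red cell index was 1.23 higher with imatinib and miR-451a alone 0.84, so miR-23a-3p was also part of the difference. With the index as a covariate all 3 calls were lost. The red cell list holds miR-451a of the index, so its loss there is no independent test. With the covariate the medians were -0.17 for the red cell list, 0.05 for the epithelial list and -0.30 for the endothelial list (adjusted p = 0.23).

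The miR-17 clusters were higher (median 0.26, adjusted p = 0.025; adjusted p = 0.70 with an estimated correlation), as was the miR-15 and miR-16 family (median 0.42, adjusted p = 0.047; adjusted p = 0.50 with an estimated correlation), where miR-15b-5p (0.42, SE 0.10) and miR-15a-5p (0.42, SE 0.10) passed adjusted over the list alone. The platelet list was lower (median -0.29, adjusted p = 0.043; adjusted p = 0.50 with an estimated correlation), but with no scaling its median was 0.01. It shares miR-126a-3p, miR-24-3p, miR-221-3p and miR-222-3p with the endothelial list. No member of these 3 lists passed over all miRNAs. The miR-17 call was lost without IMB pool 1 (median 0.10, adjusted p = 0.57) or DOX pool 2, and its median was 0.44 without IMB pool 3. The miR-15 and miR-16 call (adjusted p = 0.092 with the replicate block) and the platelet call (0.058) were lost with the replicate block, no scaling or Agilent's signal, the former also without DOX pools 1 or 2 or IMB pools 1 or 3 and the latter without any 1 DOX pool or IMB pools 1 or 2. With the red cell index as a covariate the medians were 0.034 for the miR-17 clusters, where the test turned direction, 0.19 for the miR-15 and miR-16 family and -0.01 for the platelet list, which holds miR-23a-3p of the index, none past the threshold.

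The let-7, miR-29, myeloid, muscle, mesenchymal, p53-responsive, liver, miR-30 and lymphocyte lists, and the list of array-bright or doubtful entries, did not pass, with camera adjusted p from 0.058 to 0.92. let-7i-5p (0.24, SE 0.06) passed adjusted over the list alone, and the let-7 list (median 0.09) passed without IMB pool 1 (median 0.30), CTRL pool 1 or CTRL pool 2. The miR-29 family passed without DOX pool 1 (median from -0.28 to -0.51, adjusted p = 0.019), and the muscle (median from 0.85 to 1.68, adjusted p = 0.037) and mesenchymal (median from -0.14 to -0.30, adjusted p = 0.035) lists without IMB pool 3. For the miR-30 family the median was -0.02 and the mean 0.02. miR-7058-5p differed by 1.25 (SE 0.21, adjusted p = 0.072), miR-133b-3p by 0.68 (SE 0.85), miR-128-3p by -0.41 (SE 0.17) and miR-494-3p by 0.19 (SE 0.40), none past the threshold.

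At an unadjusted p under 0.05, limma gave 17 higher and 15 lower miRNAs, and the groups did not overlap for 15.0% of miRNAs. Chance gives at most 10%, and less where values tie at the floor. The miRNAs are not independent, and the excess was not tested. The count of 3 became 0 with the red cell index as a covariate, where miR-144-3p was at 1.04 and miR-34a-5p at -1.92 (both adjusted p = 0.26). The index did not overlap between the drugs, so this covariate can hardly separate red cell content from the drug given. The count was 5 with Agilent's signal or a lower floor, 6 with mean log2 probe values, 16 with array quality weights and 20 without IMB pool 1. Over the 3 comparisons 14 of 48 list tests passed with camera's preset correlation, 0 with an estimated correlation and 0 by fry's test of a shared direction. Fry's test of change in either direction passed for the p53-responsive list for doxorubicin against control (adjusted p = 0.00050) and between the drugs (6.9e-05), the red cell list for imatinib against control (0.0017) and between the drugs (0.00096), the endothelial list between the drugs (0.0065) and the let-7 family for doxorubicin against control (0.045). In the p53-responsive list miR-34a-5p was the only member past the threshold in both comparisons, and in the red cell list for imatinib against control the 7 members other than miR-144-3p had unadjusted p from 0.25 to 0.97.

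Across the 294 miRNAs, which are not independent replicates, the drugs' differences from the controls had r = 0.57 and a Spearman rho of 0.49. Both use the same 2 control pools, and simulated unchanged groups sharing those controls gave r = 0.60 (95% range 0.43 to 0.74). The covariance was 0.0703 against a simulated 0.0407 (95% range 0.0256 to 0.0637). The simulated noise was independent between miRNAs, while measured miRNAs vary together, so these ranges may be too narrow. A covariance above its range therefore does not show a shared response to the drugs. The sign was the same for 71.1% of miRNAs against 70.5% simulated. miRNAs with values tied at the floor were not left out of this share, and the simulation applied no floor. The share therefore does not measure agreement in direction. No miRNA passed in both comparisons, where independent lists of these sizes share 0.0102.

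**Figure D3:**
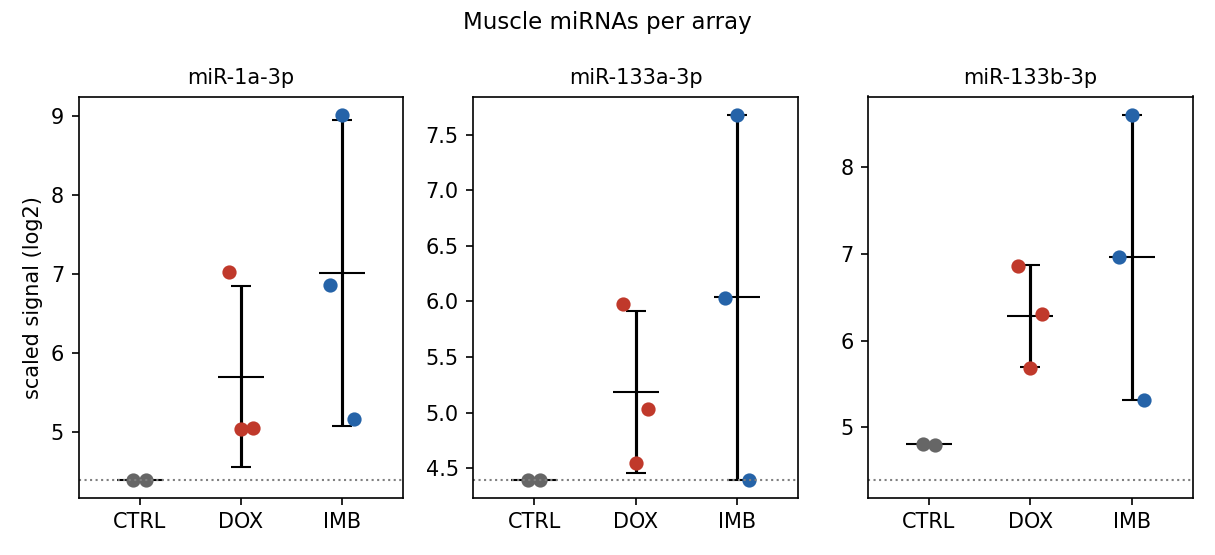
Scaled signal (log2, vertical axis) of miR-1a-3p, miR-133a-3p and miR-133b-3p by group; points are pools, horizontal bars means, whiskers SD and the dotted line the floor of 4.40. IMB pool 2 reaches 9.02 for miR-1a-3p, and both control pools are at the floor for miR-1a-3p and miR-133a-3p.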

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

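The criterion used in this part was chosen after the data were seen, and no test was run. Among 63 miRNAs that were detected on some array but entered no comparison, 25 were detected on neither control array. Of these, 5 were detected on at least 2 arrays of a drug: miR-1907, miR-3058-3p, miR-6402, miR-7211-3p and miR-8099, each on IMB pools 2 and 3 and on 0 DOX arrays. They were singled out as detected outside the comparisons and on no control array, and the sizes of their signals were not compared. IMB pools 2 and 3 lie in row 2 of the slide, as do DOX pool 3 and CTRL pool 2. The 75th percentile of the signal before scaling was 425 on IMB pool 2 and 320 on IMB pool 3, against 300 and 349 on the control arrays.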

How the results depend on the processing

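Leaving out miRNAs with a value at the floor was chosen after the data were seen; the other settings were planned. For imatinib against control, the count of 3 was 1 with Agilent's signal per miRNA, quantile normalization, a floor 4 times lower, the authors' table or no value at the floor, 5 with array quality weights, and 0 with the percentile over all probes, no scaling, scaling to miR-23a-3p and miR-24-3p, no filter or the red cell index as a covariate. For doxorubicin against control, the count of 1 was 2 with Agilent's signal, the percentile over all probes, a floor 4 times lower or the authors' table, and 0 with no filter, only the compared groups, the replicate block, the red cell index as a covariate or no value at the floor, which leaves miR-34a-5p out. Between the drugs, the count of 3 was 5 with Agilent's signal or a floor 4 times lower, 6 with mean log2 probe values, 16 with array quality weights and 0 with the red cell index as a covariate. The 14 list calls became 0 with an estimated correlation, 0 by fry's test of a shared direction, 9 with Agilent's signal and 0 with the red cell index as a covariate, whose miRNAs belong to the red cell and platelet lists. With that covariate the test of the miR-17 clusters between the drugs turned direction, at a median of 0.034 (adjusted p = 0.97; 6.2e-05 to 0.97 over its alternatives). The cause was not tested. Since the index differed between the groups, a call lost with this covariate does not show that red cell content produced it.

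Leaving out each array gave 0 to 12 calls for imatinib against control, 0 to 2 for doxorubicin against control, 3 to 20 between the drugs and 8 to 16 list calls (8 without DOX pool 2). Where this left 1 control pool, it was assumed to vary like the other groups. For the correlation of the drugs' differences only the control pools were left out, which gave 0.61 without CTRL pool 1 and 0.64 without CTRL pool 2, with no simulated value beside them. Detected miRNAs differed by -27.0 to 9.50 for imatinib and by -57.7 to -27.7 for doxorubicin against control, and by 15.7 to 52.2 between the drugs; the red cell index differed by 0.24 to 0.90, -0.99 to -0.33 and 1.05 to 1.38. miR-34a-5p kept its call in 17 of 21 alternatives against control and 20 of 21 between the drugs, miR-144-3p in 11 of 22 and 20 of 22, miR-202-3p in 8 of 20 and 11 of 20, and miR-7058-5p in 16 of 22. The median miRNA moved by over 0.1 with no scaling (-0.32 for doxorubicin against control, 0.23 between the drugs), with scaling to miR-23a-3p and miR-24-3p (0.19 for imatinib against control, 0.30 between the drugs) and with normexp (0.11 for doxorubicin against control). Same-numbered pools of different groups correlated at -0.24 to 0.40 (7 pairs, mean 0.06) and the others at -0.46 to 0.47 (14 pairs, mean -0.03). With so few pools this does not settle whether the numbers pair them. With the replicate block the counts were 2, 0 and 4. The slide as a block was not run, with 1 slide. Signal over background limits values near the floor.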

Other observations

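The miRNAs named in this paragraph were chosen after their values were seen. On both control arrays and no DOX array 15 miRNAs were detected, among them miR-132-3p, miR-146b-5p, miR-186-5p, miR-331-3p and miR-532-5p. These 5 were near the detection limit, at the floor of 4.40 on every DOX array and at most 4.43 on the control arrays, and the 75th percentile of the signal before scaling was 213 to 267 on the DOX arrays against 300 and 349 on the control arrays. On both control arrays and no IMB array it was 1, miR-423-3p, which is also among the 15 and was at the floor on all 8 arrays. On all 3 arrays of either drug and no control array it was 0. miR-144-3p and miR-451a come from neighbouring genes, and miR-144-3p minus miR-451a differed between the drugs by 0.36 (SE 0.23, 95% interval -0.22 to 0.94).

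All tests below of explanations were chosen after the results were seen, including the reading of the count over splits of the pools. The mean of the muscle list lay above both controls in 6 of 6 treated pools, by 1.66 on average, although miR-133a-3p was at the floor in IMB pool 3 as in both controls. In both controls miR-1a-3p was at the floor too, and the control mean of the list was 4.53 against a floor of 4.40. A treated pool could hardly lie lower, so the count of 6 of 6 says little about direction. The values argue against scaling, since the lowest median difference over both drugs and 4 other scalings was 1.05, where the median miRNA moved by at most 0.32. RNA of 1 muscle source entering single pools is a candidate explanation: over the 6 treated pools the lowest of 3 pairwise correlations was r = 0.951 (exact permutation p = 0.015, adjusted 0.015; rho 0.77, exact p = 0.10, adjusted 0.10; r = 0.80 without the 2 farthest pools). That test does not separate muscle RNA released under a drug from muscle RNA carried over at sampling. The drugs given stay open (exact permutation p = 0.107, smallest possible 0.0357), and the floor in the controls limits that test as well.

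The red cell list was lower with doxorubicin than with imatinib by camera at its preset correlation (adjusted p = 6.1e-06). It did not pass with an estimated correlation (camera adjusted p = 0.52) or by fry's test of a shared direction (adjusted p = 0.13). Red cell lysis or carry-over may contribute to the 6 members other than miR-144-3p and miR-451a, whose mean followed miR-451a within groups with a slope of 0.744 (95% interval 0.26 to 1.23). For miR-144-3p the slope was 0.184 (95% interval -0.05 to 0.42), and the bound set for this test was amended after its result, because a call favours a small spread and only 15.3% of tested miRNAs had a residual SD at or below that of miR-144-3p. Lysis therefore stays open for miR-144-3p. The drugs given stay open too (exact permutation p = 0.1, the smallest possible).

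miR-34a-5p was higher with doxorubicin. The values argue against scaling as the cause, since the lowest log2 difference over 5 other scalings was 2.20, each past the threshold; the size rests on the treatment of low values, being 1.09 with normexp background correction (adjusted p = 0.0055). They argue against cross-hybridisation of miR-34b-5p, miR-34c-5p or miR-449a-5p, detected on 0 of the DOX arrays. A shared rise of p53-responsive miRNAs stays open (limma fry p = 0.296; exact permutation p = 0.4 for a mean difference of 0.20, smallest possible 0.1), with 4 of the other 6 tested members higher. A response of miR-34a-5p to doxorubicin may remain as a hypothesis, found and tested on the same pools, and 7 of 50 simulations with no change gave as many calls.

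Between the drugs, the real split of the 6 treated pools gave 3 miRNAs past the threshold and the highest of the other splits 2, so 1 of 10 splits gave as many. With 10 splits a share under 0.05 cannot be reached.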
